A study of Mus musculus with 8 samples.

How the data were processed

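The data are ATAC-seq counts from 8 libraries of C57BL/6 mouse iTreg cells, 4 transduced with a guide labelled sgNTC and 4 with sgCcdc101, per the labels. The labels' protocols describe sorting, overnight restimulation with anti-CD3 (0.25 µg/ml) and anti-CD28 (5 µg/ml), lysis with a detergent, transposition for 30 min at 37 °C and 5 amplification cycles in the barcoding reaction. The authors deposited 1 table of whole-number counts per region for all libraries, with chromosome, start and end of each region and no scaling between libraries. The submitters' processing notes name cutadapt 1.9, Picard 1.65, SAMtools, MACS2 2.1.0.20150603 and bedtools, with no role or order, and the builds mm9 and NCBIM37. The aligner, the read filters, any shift of reads for the transposase, and how regions were joined across libraries are not given in the sources used here. Between 77.9% and 82.3% of the counts in each library were even, as fragments counted at both ends would give.

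The table held 79759 regions on 21 chromosomes, 2 to 2412 bp long with a median of 320 bp. Positions reached 197059159 on chromosome 1, which fits mm9. Coordinates are printed as the table lists them. Whether its starts count from 0 or 1 is not given in the sources used here, so a start may be off by 1 bp. The gene table at hand is of GRCm38.p6, another build, and no annotation or sequence of mm9 was used. Regions therefore carry no gene names, and promoter and distal regions, the 17 gene lists fixed beforehand, regions of the target gene and GC content were not analysed here.

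Regions were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, after its filterByExpr filter by group, which kept 71317 regions and left out 8442. Factors came from TMM, dispersions from estimateDisp, and p-values from the quasi-likelihood F test of sgCcdc101 against sgNTC with no covariate, adjusted by Benjamini-Hochberg. A region was called at an adjusted p under 0.05. The common dispersion gave a coefficient of variation of 12.3%. CPM values are TMM-scaled, and the standard error of a log2 fold change was taken as its size divided by the square root of F. The design, the alternatives and the rule for named regions were set before the data were examined. The rule takes, among called regions with a mean log2 CPM at or above the median of tested regions, the 12 with the largest positive and the 12 with the largest negative log2 fold change, by coordinates.

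The test was checked on simulated counts of 71317 regions with the means and library sizes of this comparison. It recovered 66% of 50 regions raised 2-fold and 62% of 50 lowered 2-fold, 12% of 50 raised 1.5-fold and 12% of 50 lowered 1.5-fold, and called 4 of 71117 unchanged regions. Of the 2-fold changes it recovered 17 of 48 in regions below the median strength and 47 of 52 above it, and of the 1.5-fold changes 0 of 51 and 12 of 49. With 200 changed regions, the adjusted threshold in that simulation is stricter than in the real comparison. All simulated libraries otherwise shared the same mean profile, with no trend with abundance between groups. Its count of false calls therefore does not cover errors of scaling. The median of the mean count per library was 11.1 in the weakest of 10 abundance classes and 325 in the strongest.

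Library measures (totals, shares of counts on the X and Y chromosomes, in the 1% of regions with most counts and in regions left out of the test, regions at 0, and even counts) were compared with two-sided exact permutation tests over the 8 libraries, adjusted over the 7 measures. Alternatives were RLE factors, total counts only, loess offsets (normalizeCyclicLoess of limma 3.58.1 on log2 CPM with a prior count of 2), DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 4 libraries, an adjusted p under 0.01, glmTreat against a fold of 1.2, the replicate number as a block, and leaving out each library. Added after seeing the data were halved counts, summed libraries, the set called under all 4 scalings, leaving out each library for the shares of counts, and tested regions only for the share in the 1% of regions with most counts. The size of calls per abundance class, chains of calls, windows of 1000000 bp and neighbour correlations were also chosen after seeing the data. So were the permutation tests on the shares of tested counts in abundance classes, which were left unadjusted. The chance levels of chains and windows came from 1000 and 100 shuffles within the 10 abundance classes. Those of neighbour correlations came from 18 splits with 2 libraries of each group on each side. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.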

Results

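Chromatin accessibility was measured by ATAC-seq, which sequences the DNA that a transposase can reach in nuclei, in C57BL/6 mouse iTreg (induced regulatory T) cells. The cells had been transduced with a guide RNA against Ccdc101 (sgCcdc101) or with a guide labelled NTC (sgNTC), an abbreviation usually used for a non-targeting control. CCDC101, also called SGF29, is a subunit of the SAGA co-activator complex, which carries a histone acetyltransferase. Sorted cells had been restimulated overnight with anti-CD3 at 0.25 µg/ml and anti-CD28 at 5 µg/ml. Each group had 4 libraries, and the table listed counts for 79759 regions of the mm9 mouse build. Total counts were 6274852, 5279650, 5501636 and 5189059 in sgNTC libraries 1 to 4, and 6287588, 5591654, 6167396 and 5473233 in sgCcdc101 libraries 1 to 4. The totals did not differ past the threshold (two-sided exact permutation test, p = 0.314, adjusted p = 0.314 over 7 library measures). The targeted gene's own regions were not looked up, because no annotation of this build was used here, so the guide's effect at its target was not checked.

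The question the series states is how accessibility differed between sgCcdc101 and sgNTC cells. Regions changed in both directions across every autosome and the X chromosome. Of 71317 tested regions, 16495 were more accessible in sgCcdc101 cells (23.1% of tested regions) and 13706 were less accessible (19.2%). The regions that rose had a median log2 fold change of 1.15, and those that fell a median of -0.65. These medians cover called regions only and depend on what could be called, since 50.5% of the gains but 11.7% of the losses lay in the weaker 5 of 10 classes of mean log2 CPM, where only larger changes passed. The smallest gain called was 1.03 (log2) in the weakest class and 0.19 in the strongest, and the smallest losses were -1.03 and -0.16. Within classes the median gain was larger than the median loss in 9 of 10, with 1.63 and -1.34 in the weakest, but in the strongest class the medians were 0.48 and -0.61. With loess offsets 37.3% of the gains and 30.0% of the losses lay in the weaker 5 classes, and the median gain was the larger in all 10 classes. A change of at least 2-fold was reached by 10083 regions that rose and by 1425 that fell, and a change of at least 4-fold by 1688 and by 21. These calls came from edgeR's quasi-likelihood test with TMM scaling and a Benjamini-Hochberg adjusted p under 0.05, and together make 30201 regions, or 42.3% of those tested. All 4 sgCcdc101 libraries lay above all 4 sgNTC libraries in 14546 tested regions and below them in 12306. Together these make 37.7% of the tested regions. Chance would give 2.86% if the libraries were independent, which the labels do not show. The direction split depended on scaling: 54.6% of the calls were gains with TMM, 51.3% with RLE factors and 51.0% with DESeq2. Scaling by total counts only gave 71.2% (22345 gains and 9026 losses) and moved the median log2 fold change of all tested regions from 0.06 to 0.27. In an alternative chosen after the data were examined, libraries were summed if their region counts differed by no more than counting noise once trends with abundance were removed. The median log2 fold change of all tested regions was then 0.05. That fit sets 1 summed sgCcdc101 library, assumed to vary like those of sgNTC, against 2 sgNTC libraries.

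With TMM, calls in strong regions were mostly losses and calls in weak regions mostly gains. Tested regions were divided by mean log2 CPM into 10 classes of equal size. In the strongest class, 82.2% were less accessible in sgCcdc101 cells and 5.76% more, with a median log2 fold change of -0.55. In the weakest class, 19.3% were more accessible and 2.87% less, with a median of 0.34. The median fell from class to class, through 0.19 in the fifth and 0.03 in the eighth to -0.24 in the ninth. The strongest class held 54.4% ± 1.31 (SD, n = 4) of the tested counts in sgNTC and 44.1% ± 0.425 (SD, n = 4) in sgCcdc101. The weaker 5 classes held 9.73% ± 0.538 (SD, n = 4) and 13.8% ± 0.19 (SD, n = 4). Both differences gave an unadjusted p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 against 4 libraries allow. These tests were chosen after seeing the data and lie outside the 7 library measures that were adjusted. Their classes were formed from the same counts. The 798 regions with the highest mean counts, 1% of the table, held 13.2% ± 0.428 (SD, n = 4) of all counts in sgNTC and 9.97% ± 0.143 (SD, n = 4) in sgCcdc101 (two-sided exact permutation test, p = 0.0286, adjusted p = 0.05 over 7 library measures, which is not under the threshold of 0.05). Of the regions over 600 bp, 56.4% were less accessible and 14.2% more, against 4.06% and 15.7% of the regions up to 250 bp. With loess offsets the shares over 600 bp were 31.1% and 22.8%. Up to 250 bp they were 9.98% less and 8.24% more accessible, so that the direction in short regions turned.

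Loess offsets are fitted to remove a trend with abundance, and therefore say nothing about whether the trend itself holds. With them, 31.2% of the strongest class were less accessible and 25.1% more, and the median there was -0.05. In the weakest class, 9.18% were less accessible and 8.41% more, with a median of -0.08, so that the direction there turned. The count of changed regions was then 26273, with 14354 gains and 11919 losses. Of the 30201 regions called with TMM, 21308 were called in the same direction with loess offsets (70.6%) and 680 in the opposite direction. Gains of at least 2-fold numbered 7111 with loess offsets, and losses of at least 2-fold 2845. Across 4 scalings (TMM, RLE, total counts and loess), 12170 regions were more accessible under each of them and 6238 less accessible. In the strongest class these numbers were 356 and 2228. Total counts only gave 9026 losses in all, which limits the losses in this set. TMM and loess offsets alone shared 12406 gains and 8902 losses, so the balance of gains and losses in the set depends on the scalings included.

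**Figure D1:**
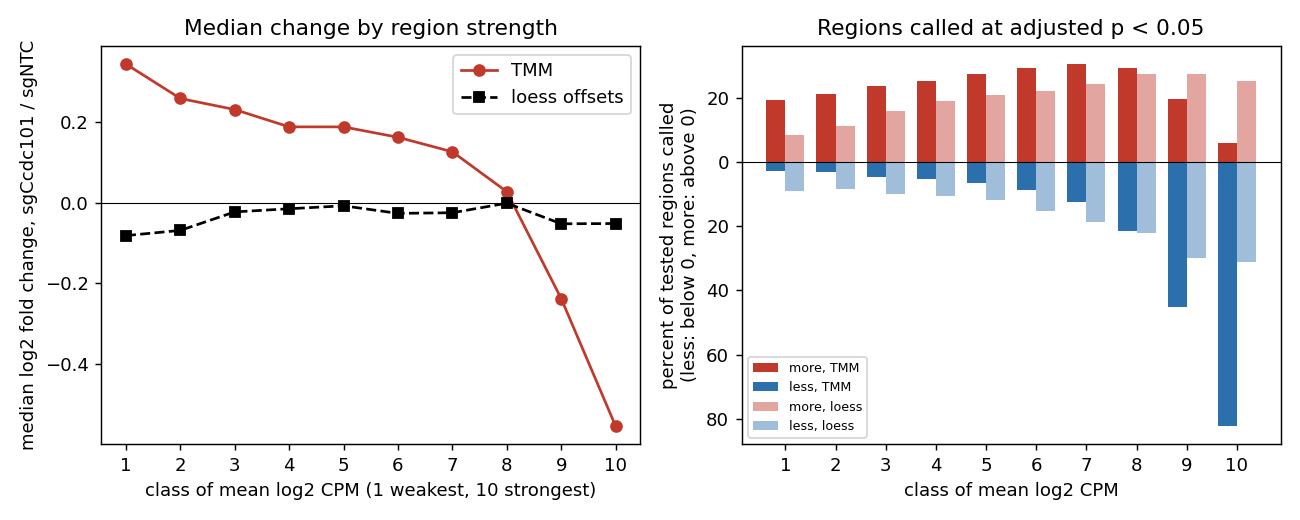
The left panel plots the median log2 fold change of sgCcdc101 over sgNTC in each of 10 classes of mean log2 CPM, from weakest (1) to strongest (10), for TMM scaling and for loess offsets, and the right panel the percent of tested regions called more (above 0) or less (below 0) accessible. With TMM the median runs from 0.34 to -0.55, and with loess offsets no class lies below -0.08 or above 0.

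Among regions at or above the median strength, the 12 largest gains had low counts in sgNTC cells. The largest was at X:160376514-160377076, a 562 bp region with 0.663 ± 0.298 CPM (SD, n = 4) in sgNTC and 15.5 ± 1.53 CPM (SD, n = 4) in sgCcdc101. Its log2 fold change was 4.47 ± 0.30 (SE), with an edgeR adjusted p of 3.03e-22. Of the other tested regions within 50 kb of it, 2 in number, both were called less accessible. The next was at 5:28723005-28723341, with 0.769 ± 0.257 and 9.9 ± 2.35 CPM (SD, n = 4 each), followed by 4:116696154-116696608 with 0.86 ± 0.872 and 10.4 ± 1.15 CPM. The region at 11:34294975-34295375 rose from 0.914 ± 0.754 to 9.73 ± 2.88 CPM, and all 5 of its tested neighbours within 50 kb rose as well. At 5:151976076-151976751 the sgCcdc101 libraries lay closer together than at any other of the 12 gains, with 1.85 ± 0.648 CPM in sgNTC and 18.2 ± 0.33 CPM in sgCcdc101, and 6 of its 7 neighbours rose. The other 7 gains were at 1:108481896-108482275, 4:95268541-95268960, 13:8805157-8805563, 14:14862102-14862649, 7:50596091-50596495, 17:78513729-78514182 and 4:122624563-122624911. Over the 12 gains the log2 fold changes ran from 3.06 to 4.47, or 8.31-fold to 22.1-fold, with edgeR adjusted p-values of at most 5.57e-14. These folds rest on 0 to 24 counts per sgNTC library. The log2 fold change at 4:116696154-116696608 went from 3.55 to 4.29 without sgNTC 3, that at 11:34294975-34295375 from 3.31 to 4.07 without sgNTC 1, and that at 4:122624563-122624911 from 3.06 to 3.67 without sgNTC 4. Over the 12 gains and each library left out, the values ran from 2.76 to 4.74. Group means ran from 0.663 to 2.24 CPM in sgNTC and from 9.73 to 19.5 CPM in sgCcdc101.

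The 12 largest losses among regions at or above the median strength were smaller and left residual signal. At 9:110809868-110810363 accessibility fell by 2.07 ± 0.23 (SE) on the log2 scale, from 13.8 ± 2.52 CPM (SD, n = 4) in sgNTC to 3.27 ± 0.529 CPM (SD, n = 4) in sgCcdc101, with an edgeR adjusted p of 1.06e-12. The region at 15:5282849-5283492 fell from 10.3 ± 0.602 to 2.62 ± 1.35 CPM, and the one at 2:139877383-139877986 from 15.8 ± 1.49 to 4.03 ± 1.19 CPM. The last of these lay among gains, since 8 of its 12 tested neighbours within 50 kb rose and 1 fell. The region at 5:114120617-114120995 fell from 11 ± 2.28 to 2.81 ± 0.501 CPM. The strongest of the 12 were at 1:69738590-69739335, with 30.9 ± 3.16 CPM in sgNTC and 8.97 ± 2.46 CPM in sgCcdc101, and at 10:118438321-118438898, with 28.4 ± 3.27 and 8.95 ± 1.59 CPM. The remaining 6 were at 15:5727059-5727535, 17:6986534-6986765, 15:97987747-97988078, 14:101852166-101852618, 6:67077813-67078176 and 2:35837419-35837712. Over the 12 losses the log2 fold changes ran from -2.07 to -1.67, or 3.17-fold to 4.21-fold lower, with edgeR adjusted p-values of at most 5.1e-08. The groups did not overlap in any of the 24 regions, which were picked from these same values for their large changes. Of 98 tested neighbours of the 12 gains within 50 kb, 44 rose and 11 fell, and of 93 neighbours of the 12 losses, 21 fell and 25 rose. Among all tested regions 23.1% rose and 19.2% fell, so the neighbours of the losses lay near these shares, while those of the gains rose more often.

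**Figure D2:**
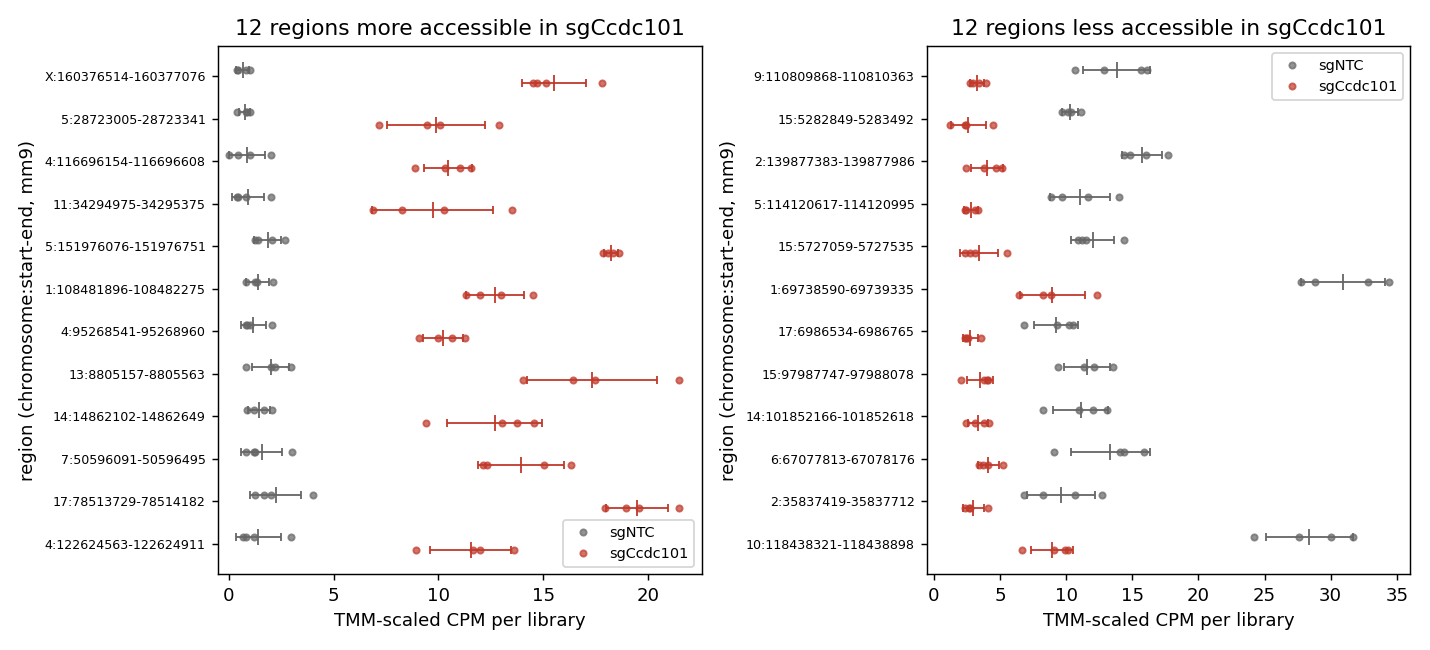
Each dot is the TMM-scaled CPM of one library in one of the 24 named regions, with the group mean and SD as bars, sgNTC in grey and sgCcdc101 in red. In the gains every sgNTC library lies at or below 4.02 CPM and every sgCcdc101 library at or above 6.87 CPM.

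Median changes of whole chromosomes were small. With TMM the median log2 fold change per autosome ran from -0.04 on chromosome 11 to 0.17 on chromosome 18, and with loess offsets from -0.12 to 0.07 on the same 2 chromosomes. On chromosome 11, 18.5% of tested regions were more accessible and 25.2% less. On chromosome 18 the shares were 28% and 15.6%. The X chromosome had 1806 tested regions, 22.6% more and 16.8% less accessible, with a median of 0.08 that turned to -0.05 with loess offsets. Of the 12 tested regions on the Y chromosome, 4 were more accessible and 0 less by edgeR. The X chromosome held 2.04% ± 0.0352 (SD, n = 4) of all counts in sgNTC and 2.12% ± 0.0313 (SD, n = 4) in sgCcdc101, a difference that did not pass the threshold (two-sided exact permutation test, p = 0.0571, adjusted p = 0.0799). The Y chromosome's 13 regions held 0.00955% ± 0.00103 and 0.0133% ± 0.00042 (SD, n = 4 each; two-sided exact permutation test, p = 0.0286, adjusted p = 0.05 over 7 library measures, not under the threshold).

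**Figure D3:**
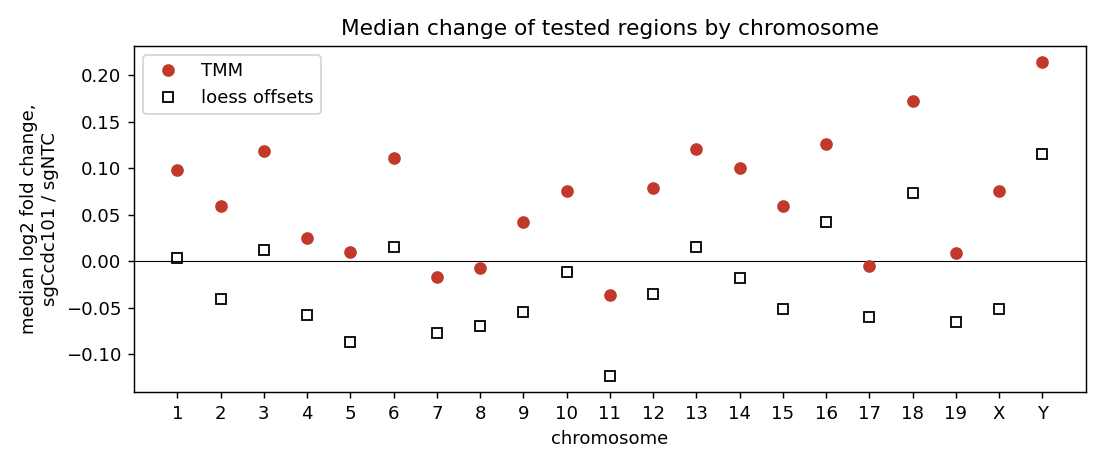
Each point is the median log2 fold change of sgCcdc101 over sgNTC among the tested regions of one chromosome, with TMM scaling (red circles) or loess offsets (open squares). Among autosomes, chromosome 11 is lowest and chromosome 18 highest under both.

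Several stretches of the genome changed in one direction over many kilobases. They were picked after the values were seen, as the longest chains of called regions of one direction with midpoints at most 10000 bp apart. Their length alone does not set them apart, since the longest chain held 13 regions in each direction and shuffled calls gave chains of up to 15. The steepest gain was at 15:31259616-31279984, where all 9 tested regions rose over 20.4 kb with a median log2 fold change of 1.89. Its summed accessibility was 18.9 ± 1.41 CPM (SD, n = 4) in sgNTC and 63.2 ± 9.36 CPM (SD, n = 4) in sgCcdc101. At 7:65964747-66014989, 13 of 16 tested regions rose and 1 fell, from a sum of 180.1 ± 10.7 CPM to 265 ± 4.09 CPM. At 2:151354932-151413996, 12 of 15 rose and 1 fell, from 214 ± 12.9 to 294 ± 14.9 CPM. Among losses, 13 of 15 regions at 13:23622082-23678060 fell and 0 rose by edgeR, and the sum went from 513 ± 11.8 CPM in sgNTC to 359 ± 14 CPM in sgCcdc101. All 10 regions at 11:87550299-87573388 fell, from 445 ± 29.1 to 274 ± 10.6 CPM. At 10:79601855-79643054, 9 of 13 fell and 1 rose, but with loess offsets 4 fell and the median was -0.07. In the other 5 stretches, loess offsets left 8 to 11 regions called in the same direction, and 1 region was called in the opposite direction in each of those on chromosomes 7, 2 and 13. On chromosome 13 it was 13:23646736-23648470, which went from -0.22 to 0.25.

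**Figure D4:**
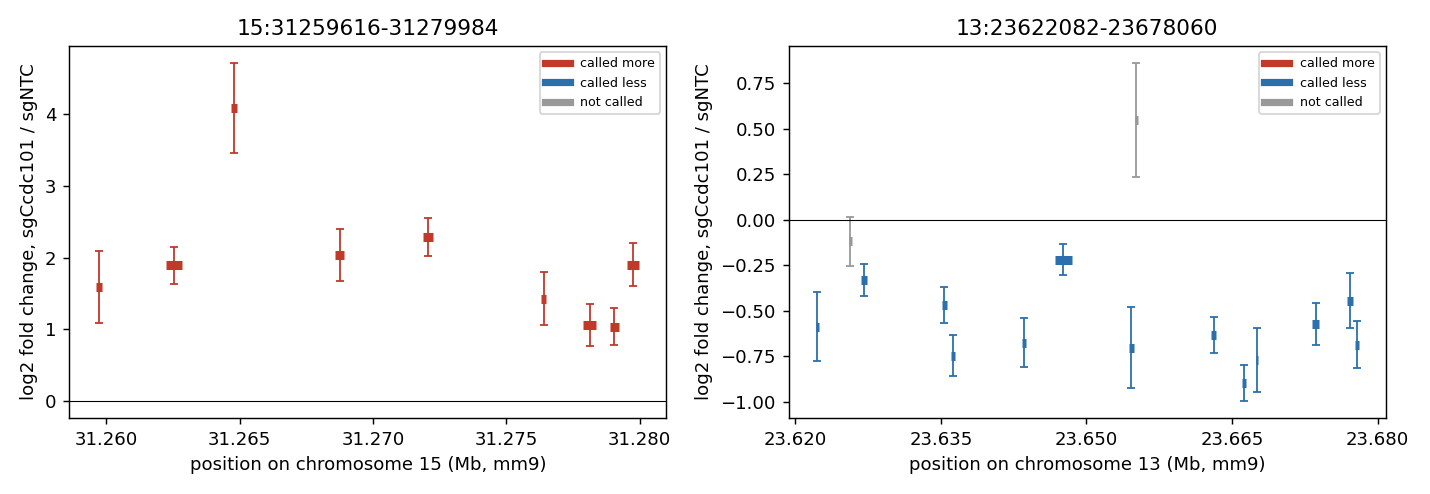
Each bar spans one tested region and gives its log2 fold change of sgCcdc101 over sgNTC (TMM), with its SE as whiskers, red where called more accessible, blue where called less and grey where not called. The left panel shows the 9 gains at 15:31259616-31279984 and the right panel the 13 losses among 15 regions at 13:23622082-23678060.

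The libraries of a group resembled each other closely. Spearman correlations of counts ran from 0.909 to 0.924 within groups and from 0.819 to 0.847 between them, and the first principal component of log2 CPM took 54.1% of the variance and separated the groups. For sgCcdc101 pairs and for pairs among sgNTC 2 to 4, the index of dispersion of region counts was 1.94 to 2.03 after removing trends with abundance, where 2 is the counting noise of fragments counted at both ends. It was 2.11 to 2.39 for pairs that include sgNTC 1. All 12 within-group pairs nevertheless differed in how counts were spread over 50 bins of abundance. A chi-square test against counting noise alone, its statistic divided by 2 for fragments counted at both ends, gave p-values of at most 0.00526. Each library was kept as 1 sample, but these differences do not show that the libraries of a group are independent. The labels do not say whether the 4 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.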

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

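The tests of explanations below were chosen after the results they bear on were seen.

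Among the 24 named regions and the library measures, 66 groups of 4 libraries were searched for 1 library far from the rest, and 3 stood out where chance gives about 3.3. At 4:95268541-95268960, sgNTC 2 had 2.06 CPM and the other sgNTC libraries 0.806 to 1 CPM. At 17:6986534-6986765, sgCcdc101 2 had 3.59 CPM and the others of its group 2.37 to 2.58 CPM. At 15:97987747-97988078, sgCcdc101 1 had 2.07 CPM and the others 3.78 to 4.11 CPM.

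The 8442 regions left out of the test for low counts held signal that the comparison did not use. They took 1.49% ± 0.0369 (SD, n = 4) of all counts in sgCcdc101 and 0.861% ± 0.0646 (SD, n = 4) in sgNTC (two-sided exact permutation test, p = 0.0286, adjusted p = 0.05 over 7 library measures), and 6766 of them had a higher CPM in sgCcdc101. Regions with 0 counts numbered 203 ± 39.5 (SD, n = 4) in sgCcdc101 and 1197 ± 386 (SD, n = 4) in sgNTC (two-sided exact permutation test, p = 0.0286, adjusted p = 0.05). Neither adjusted p is under the threshold of 0.05.

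Strong regions were lower and weak regions higher in sgCcdc101 cells, a gap of -0.808 between groups in the log2 ratio of the share of counts in the strongest of 10 abundance classes to that in the weaker 5. A uniform background added to the sgCcdc101 libraries as the only cause is argued against. A scaled sgNTC signal plus counts in proportion to region width missed the weakest class by -0.329 (bootstrap SD 0.00542), with fewer sgCcdc101 counts there than that model gives. It missed the eighth class by 0.274 in the other direction. The bootstrap resampled regions, so its SD does not measure the spread between libraries. A background that is not uniform was not tested. A difference in total counts over the listed regions is argued against as well. In the 4 library pairs where the sgCcdc101 library had the lower total, the mean gap was -0.704 (SD 0.138). Most of these pairs share sgNTC 1, so that SD is not a spread over independent pairs. Over all 16 pairs between groups the smallest gap was -0.605. The totals cover the listed regions only, so sequencing depth itself was not tested. An unequal balance of tagmentation between preparations cannot be told apart from an effect of the guide: sgNTC 1 differed from sgNTC 2 to 4 by a gap of -0.213 whose profile over the 10 classes had a correlation of 0.993 with that between the groups, so libraries of 1 group can vary along this axis, though by less.

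Of the tested regions, 42.3% were called. Only the real one of 35 splits of the 8 libraries gave as many as 30201 changed regions, 16495 gains and 13706 losses. That is 1 of 35 in each case, the smallest share these splits allow. It argues against a chance division of the libraries only at that level, and not against chance at any single region. The highest count of the 34 other splits was 0 by edgeR's quasi-likelihood test and 0 by limma-voom. Those splits put libraries of both groups on a side, so that the difference between the groups widens their spread. Their counts of 0 therefore give no chance level. At an unadjusted edgeR p under 0.05 they gave 560 to 7536 regions, which is no chance level either, and the real split gave 34626. Evenly spread p-values would give 3566. A difference in scaling with abundance as the only source of calls is argued against, since 70.6% of them were still called in the same direction with loess offsets. A preparation or culture difference that coincides with the guide cannot be told apart from the guide, because no label separates the 2. The groups lay fully apart on the first principal component (54.1% of variance), which either could give, so that separation does not decide between them.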

How the results depend on the processing

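The fit with 1 summed sgCcdc101 library is left aside in the next 2 tallies. For changed regions, gains and losses, 59 of 60 alternative counts lay within 1.5 times those reported. All 480 alternative values for the 24 named regions kept their direction and their call. These regions were picked as the largest called changes, so this says little about other calls. Leaving out 1 sgNTC library moved 3 gains by over 1.5 times (log2 fold changes of 3.55 to 4.29, 3.31 to 4.07 and 3.06 to 3.67). With total counts only, losses numbered 9026 against 13706 and gains 22345 against 16495, since the median log2 fold change of all tested regions moved from 0.06 to 0.27. With sgNTC 2 to 4 summed into 1 library and all sgCcdc101 libraries into another, an alternative chosen after seeing the data, 19499 regions were called, 10934 gains and 8565 losses. This fit has fewer libraries, and its lone sgCcdc101 library is assumed to vary like the sgNTC ones. Changed regions otherwise ran from 23640 (adjusted p under 0.01) to 31833 (no filter), with 30253 for RLE, 26273 for loess offsets, 27541 for DESeq2 and 29479 for limma-voom. Leaving out each library gave 27526 to 29515 changed regions, 14806 to 15612 gains and 12720 to 13903 losses. Halved counts, chosen after seeing the data, gave 30766.

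The replicate number as a block gave 29361 changed regions, 15994 gains and 13367 losses. Deviations of same-numbered libraries had correlations of 0.0162, 0.0073, -0.000959 and -0.00377, the first of them the highest between any sgNTC and sgCcdc101 library. Of 4 sgNTC libraries, 2 correlated best with their own number. Region counts within groups differed by little more than counting noise, so correlations near 0 cannot tell whether the numbers pair the libraries.

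Leaving out each library, an alternative chosen for these shares after seeing the data, the difference in the percent of counts (sgCcdc101 minus sgNTC) ran from 0.0033 to 0.00405 on the Y chromosome and from -3.48 to -3.15 in the 1% of regions with most counts. Both kept their direction, with an unadjusted p of 0.0286 over all libraries (adjusted p = 0.05 over 7 measures, not under the threshold), while 4 against 3 libraries allow no exact permutation p under 0.0571. On the X chromosome it ran from 0.0696 to 0.0954. Tested regions only gave 0.0777 and 0.00361 for X and Y, and -3.24 for the 1% of regions, the last chosen after seeing the data. Alternatives for promoter and distal regions, gene lists and GC content were not run, for want of an annotation or sequence of this build. In simulated counts, 2-fold changes were recovered in 17 of 48 regions below the median strength and 47 of 52 above it. The adjusted threshold there was stricter than in the real comparison, so these shares do not give its sensitivity. In the real comparison the smallest gain called was 1.03 (log2) in the weakest abundance class and 0.19 in the strongest, so calls are limited in weak regions.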

Other observations

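The tests in this part were chosen after the results were seen.

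On the loess scale, gains gathered in some megabase windows. Among 1709 windows of 1000000 bp with at least 10 tested regions, 55 had a median log2 fold change over 0.5, where 100 shuffles within the 10 abundance classes gave at most 13, while 4 had a median under -0.5, where shuffles gave up to 7. The highest medians were 1.22 at 2:45000001-46000000 (9 of 11 tested regions called more accessible with loess offsets), 1.19 at 17:91000001-92000000 (11 of 18) and 1.13 at 7:122000001-123000000 (11 of 17), against at most 1.06 in the shuffles. The lowest were -0.76 at 15:60000001-61000000 and -0.62 at 10:78000001-79000000, no lower than the -0.78 that shuffles reached.

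Neighbouring regions tended to change together: chains of at least 5 gains with midpoints at most 10000 bp apart numbered 130, against at most 49 in 1000 shuffles of the calls within chromosome and abundance class, and chains of at least 5 losses 48 against at most 44 (permutation p = 0.001 for each, the smallest that 1000 shuffles can give). With loess offsets the chains numbered 111 against at most 44 and 33 against at most 23, but the longest chains, 13 regions in each direction and 10 and 8 with loess offsets, were no longer than the 15, 15, 14 and 15 that shuffles reached. Fragments shared by adjacent regions are argued against as the only cause, since neighbours 10000 to 30000 bp apart still had correlated log2 fold changes across regions (r = 0.165), where 18 splits with 2 libraries of each group on each side gave at most 0.0273. Regional base composition cannot be told apart from a change of domains, since no sequence of this build was used here and the correlation of 0.11 at 100000 to 1000000 bp, against at most 0.0458 in those splits, goes with either. Regions are not independent replicates.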
